A study of Mus musculus with 6 samples.

How the data were processed

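Poly(A)-selected RNA from mouse AKP organoids was sequenced as strand-marking libraries (NEBNext Ultra II Directional), per the labels' protocols. The authors deposited a table of estimated counts per gene, in whole numbers and not scaled between libraries. Salmon 1.3.0 and the mm10 build are named without a role, per the submitters' processing notes. The annotation release, the step from transcripts to genes, the rounding and the use of strand are not given in the sources used here. An estimated count divides reads that fit several similar transcripts among them, so that values of near-identical genes depend on that division.

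The table held 54418 Ensembl gene identifiers, of which 54096 matched a symbol and coordinates of GENCODE M21 (the assembly of mm10). The other 322 took 0.0345% to 0.0432% of the counts of a library and were kept under their identifiers. There were 24064 genes at 0 in all 6 libraries. Groups and replicate numbers came from the sample titles. No 2 libraries held the same values, with at least 23754 genes differing between any 2 of them. Total counts ran from 22973245 to 31328415 per library.

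Genes were kept by edgeR's filterByExpr with its defaults, which left 14714. These ask for the equivalent of 10 counts at the median library size in at least 3 libraries, the size of a group, and for 15 counts in total. Libraries were scaled by TMM. GATA6KO was compared with Control by the quasi-likelihood test (estimateDisp, glmQLFit with robust estimation, glmQLFTest) without a block, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. An adjusted p of a single gene is from this test throughout. The SE of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 0.245. Levels are TMM-scaled CPM (counts per 1000000 counts of a library) with the SD over 3 libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

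Before the data were examined, 33 gene lists with 593 genes were fixed, together with the main test, the alternatives and the rule for named genes. Lists with at least 2 genes tested (30 of 33) were compared with all other genes by limma's camera, 2-sided, with a preset correlation of 0.01 on log2 CPM with a prior count of 2. The p-values were adjusted over the lists. The rule named Gata6, and the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap and whose higher group reached 10 CPM, without predicted or clone-named genes (201 of the 1823 called). It also named up to 4 called members of each list with at least 1 CPM in a group, or the 2 most abundant members where none was called, and 7 regulators whatever their result. Some results that this rule or the family tests would give are not reported here. In the Wnt list Axin2, in the BMP list the Id genes, and among keratins and claudins the members given by name outside this rule, were chosen after their values were seen. Families of at least 8 tested symbols (225) were tested by 1-sided Fisher's exact tests in both directions, with adjustment over both, after the values had been seen.

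The pipeline was tested on simulated counts for this comparison, drawn for 14714 genes with 200 changed. At folds of 1.5, 2, 4 and 8 it recovered 14%, 72%, 88% and 98% of 50 changed genes each, with 10 false among 146 calls. Of 32 unchanged lists, 0 were called, and the changed list was. The simulated genes were independent and had the same spread in both groups, unlike the genes of these libraries. The simulation therefore does not give the rate of false calls, of genes or of lists, in the real data.

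Alternatives were other scalings (RLE, library total alone), DESeq2, limma-voom, no filter and a stricter filter (at least 1 CPM in all 3 libraries of a group), a test against a 1.5-fold change, no robust estimation, clone-named genes left out, the replicate number as a block, and each library left out in turn. For lists they were also an estimated correlation, fry, and genes of more than 1 list left out. After the data were seen, voom with a spread per group, a fit without chromosome 14 and counts of 4 symbol families were added. Chromosome medians used genes with at least 5 CPM in Control and a pseudocount of 0.1 CPM.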

Results

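RNA was measured in organoids, self-organising epithelial cultures, of a mouse line that the labels call AKP. The series title names loss of GATA6, a zinc-finger transcription factor of the endoderm, in colorectal cancer metastasis and lineage plasticity. There were 2 groups of 3 libraries, labelled Control and GATA6KO. The comparison asks which transcripts differ between organoids with and without the knockout. Total estimated counts were 22973245, 29685711 and 31328415 in Control replicates 1 to 3, and 29674562, 29208525 and 29339961 in GATA6KO replicates 1 to 3. No label says whether the replicates were separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

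The groups lay apart on component 1 of log2 CPM (counts per 1000000), which held 57.0% of the variance. On component 2 (18.1%) GATA6KO replicates 1 to 3 lay apart from each other, at -44.4, 52.5 and -24.0, with Control at 3.59 to 8.66. The GATA6KO libraries spread more than the Control libraries: the median SD of a gene was 0.279 against 0.0950 on the log2 scale. In GATA6KO replicate 2, genes of chromosome 14 lay at a median log2 ratio of -0.90 to the Control mean. The same median was -0.09 in GATA6KO replicate 1 and 0.04 in GATA6KO replicate 3. Mitochondrially encoded transcripts took 1.85% to 1.88% of the counts in Control and 2.07%, 2.84% and 2.81% in GATA6KO replicates 1 to 3.

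**Figure D1:**
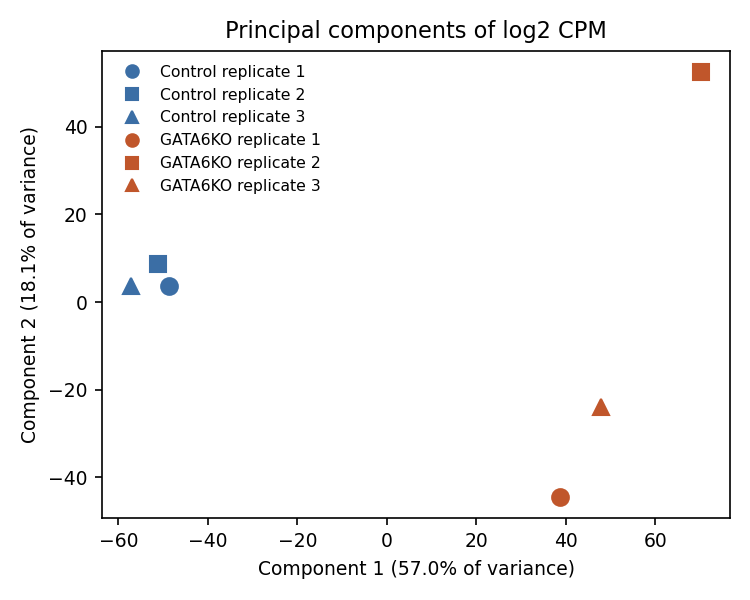
Each point is a library placed by principal components 1 and 2 of log2 CPM over the 14714 genes tested, with the colour giving the group and the shape the replicate. The 3 Control libraries lie together, and the 3 GATA6KO libraries lie apart from them on component 1 and from each other on component 2.

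**Figure D2:**
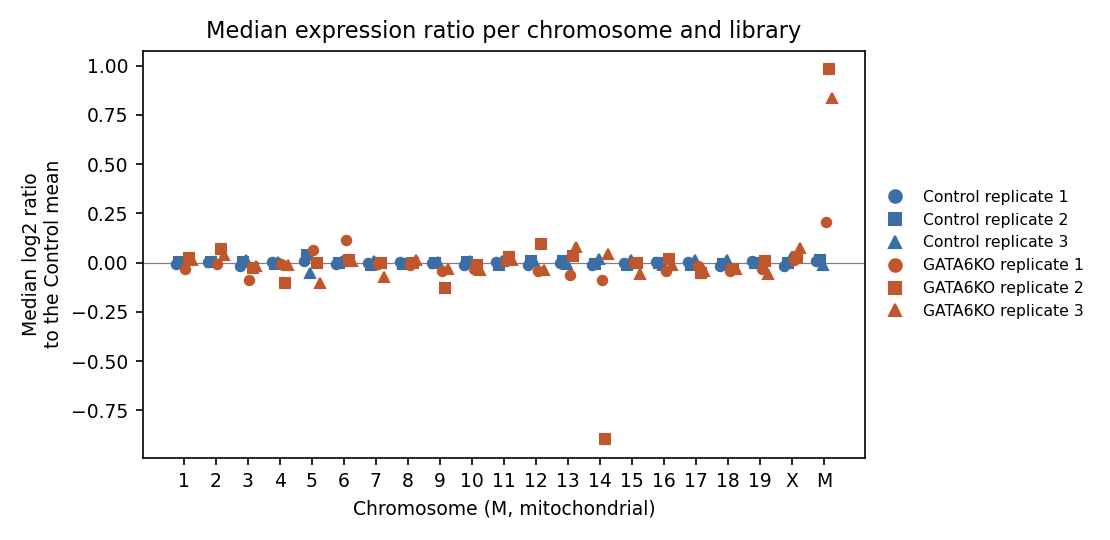
Median log2 ratio to the Control mean for the expressed genes of each chromosome (x axis, M for mitochondrial) in each of the 6 libraries, shown by colour for the group and shape for the replicate. Chromosome 14 in GATA6KO replicate 2 lies at -0.90, and no other nuclear chromosome departs from 0 by more than 0.131 in any library.

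The targeted gene was lower in every GATA6KO library. Gata6 (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635) measured 25.5 ± 2.42 CPM in Control (SD, n = 3) and 12.8 ± 4.09 CPM in GATA6KO (SD, n = 3). It had 577, 669 and 840 counts in Control replicates 1 to 3 and 427, 489 and 247 counts in GATA6KO replicates 1 to 3. Its log2 fold change was -0.99 (SE 0.25, edgeR adjusted p = 0.0486), and a 2-sided exact permutation test of the 3 against 3 values gave p = 0.1, the smallest this design allows. GATA6KO replicates 1 to 3 kept 0.560, 0.629 and 0.323 of the mean Control level. The labels do not place the lesion in the gene, and a small coding lesion need not lower a transcript. The call did not hold without Control replicate 1, 2 or 3 (edgeR adjusted p = 0.149, 0.128 and 0.181), where the log2 fold change was -0.98, -1.07 and -0.93.

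Among the related regulators, Hnf4a, an intestinal and hepatic nuclear receptor, measured 327 CPM in Control and 166 CPM in GATA6KO (log2 fold change -0.98, adjusted p = 0.0501). Cdx2, the homeobox factor of intestinal identity, measured 117 and 84.7 CPM (log2 fold change -0.47, adjusted p = 0.0536). Sox9, a factor of crypt progenitors, measured 116 and 120 CPM (log2 fold change 0.06, adjusted p = 0.763). None of these 3 passed the test. Gata4, Gata5 and Sox2 had at most 3 counts in any library and were not tested.

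The genes that rose most were mainly hair-type keratins and keratin-associated proteins. By the rule for named genes, the 10 largest increases were those of Chl1, Krt86, Krtap2-4, Lrrc15, Krtap13-1, Smpx, Krtap1-5, Krt81, Krtap3-3 and Krt34, each by a log2 fold change of at least 5.35. Krt34 (ENSMUSG00000043485, chromosome 11, 100037347 to 100041554), a hair keratin, went from 8.89 ± 1.83 to 361 ± 82.3 CPM (SD, n = 3 each; log2 fold change 5.35, SE 0.25, adjusted p = 0.000654). Chl1, a neural cell adhesion molecule, had the largest fold and SE of these 10, with 239, 792 and 12 counts in GATA6KO replicates 1 to 3 and at most 4 in a Control library.

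Large decreases were those of Cldn2, Trim35, Slc17a4, Nt5c1a, Igsf23, Tm4sf1, Lgr5, Upk1b and Gdf15, with log2 fold changes from -6.85 to -3.59. Cldn2 (ENSMUSG00000047230, chromosome X, 139800828 to 139811386), a pore-forming claudin of tight junctions, fell from 13.2 ± 1.77 to 0.110 ± 0.10 CPM (log2 fold change -6.85, SE 0.63, adjusted p = 0.00252). Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), the R-spondin receptor that marks crypt base stem cells, fell from 71.2 ± 10.7 to 5.49 ± 2.78 CPM (log2 fold change -3.70, SE 0.41, adjusted p = 0.00445). Trim35 lies on chromosome 14 and had 5, 0 and 65 counts in GATA6KO replicates 1 to 3. Of these 19 genes, 13 were called without each library in turn. Chl1, Trim35, Slc17a4, Igsf23, Tm4sf1 and Gdf15 were not called without 1 or more of Control replicates 1, 2 and 3, at adjusted p of up to 0.148 (Chl1).

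**Figure D3:**
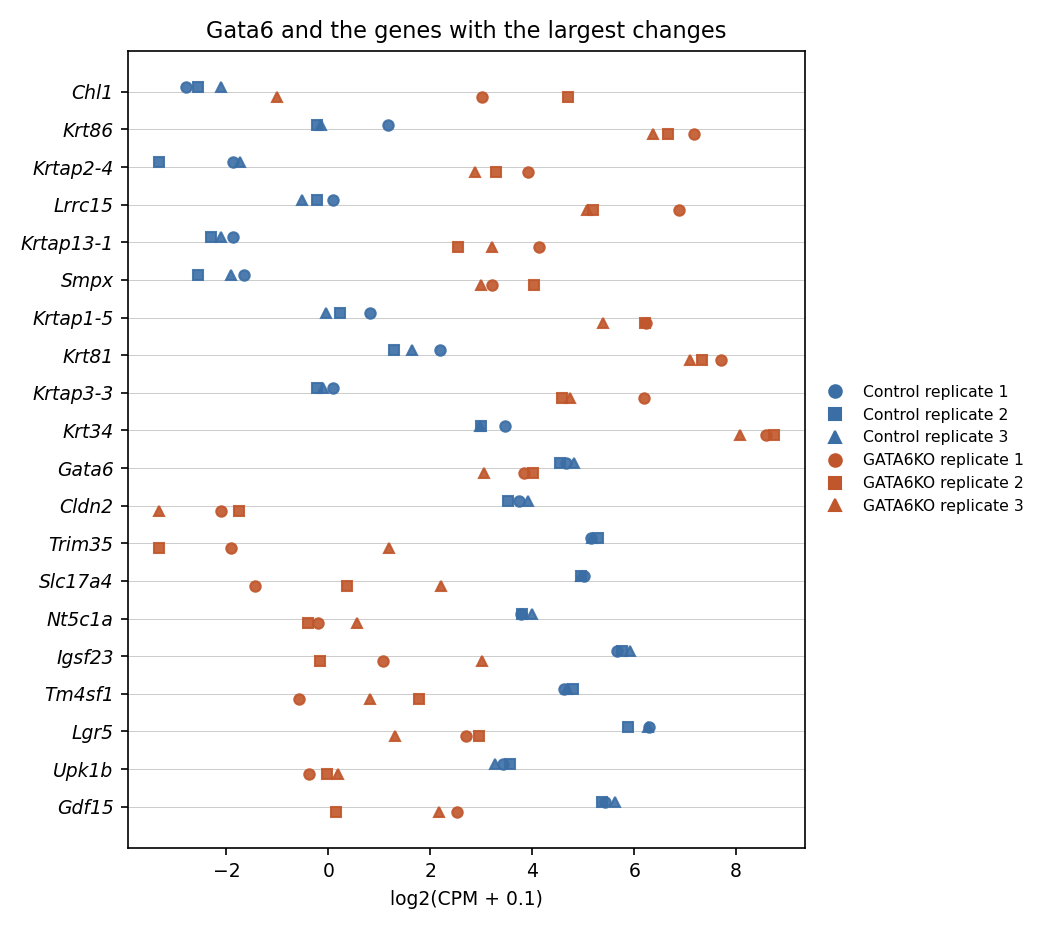
Each point is the log2(CPM + 0.1) of a gene in a library for Gata6 and the 10 largest increases and 9 genes with large decreases, with colour for the group and shape for the replicate. For all 20 genes the 3 values of a group lie on the same side of the 3 values of the other group, which the rule required of all except Gata6.

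In all, 1823 of 14714 genes tested changed between GATA6KO and Control by edgeR's quasi-likelihood test, 1018 higher and 805 lower. Of these, 593 were higher and 382 lower by a log2 fold change of at least 1. All 1823 had group values that did not overlap, as did 40.8% of all genes tested, where chance gives 10% for 3 against 3. Scaling to the library total alone called 1302 higher and 680 lower, so that the higher share went from 55.8% to 65.7%, while the median log2 fold change of all genes went from 0.02 to 0.09. Limma-voom called 875 higher and 879 lower, a higher share of 49.9%. The count of called genes by the edgeR test was 425, 389 and 332 without Control replicates 1, 2 and 3, and it was 4360 without GATA6KO replicate 1.

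Of 22 Krtap genes tested, which encode keratin-associated proteins of the hair shaft, 20 rose, each by a log2 fold change of at least 5.25. A gene near 0 in Control passes the filter mainly when it is high in GATA6KO. The share of tested Krtap genes that rose, and its test below, are thus partly set by the filter. With no filter 25 were called higher, and 44 of the 58 Krtap genes had a count. Of 29 numbered keratin genes tested, 15 rose and 3 fell. Those that rose included the hair keratins Krt34, Krt81, Krt83, Krt86 and Krt87, while Krt8, Krt18 and Krt4 fell. Krt83 went from 12.9 to 201 CPM (log2 fold change 3.97, adjusted p = 0.000759) and Krt87 from 11.8 to 315 CPM (log2 fold change 4.74, adjusted p = 0.00252). In the GATA6KO libraries the summed counts of 58 Krtap genes were 10129, 5779 and 4424, against 130, 114 and 116 in the Control libraries.

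The 7 hair keratins of type I summed to 28.4 ± 8.08 CPM of the plain library total in Control and 782 ± 59.8 in GATA6KO (SD, n = 3 each). The 6 hair keratins of type II in the table summed to 44.0 ± 16.5 and 1013 ± 148. The increased genes lay in 3 clusters of mm10, with 21 genes on chromosome 11 between 99514114 and 100135928. The others were 6 genes on chromosome 15 between 101431038 and 101562950 and 8 genes on chromosome 16 between 88728862 and 89508323. Symbol families were tested for enrichment only after the values had been seen. Fisher's exact test over 225 families gave an adjusted p of 4.82e-19 for Krtap genes and 1.67e-08 for numbered keratins among the genes that rose, and genes of a cluster are not independent. Several of these genes are near-identical copies, so values of single members such as Krt81 and Krt86 are uncertain where counting could split their reads.

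**Figure D4:**
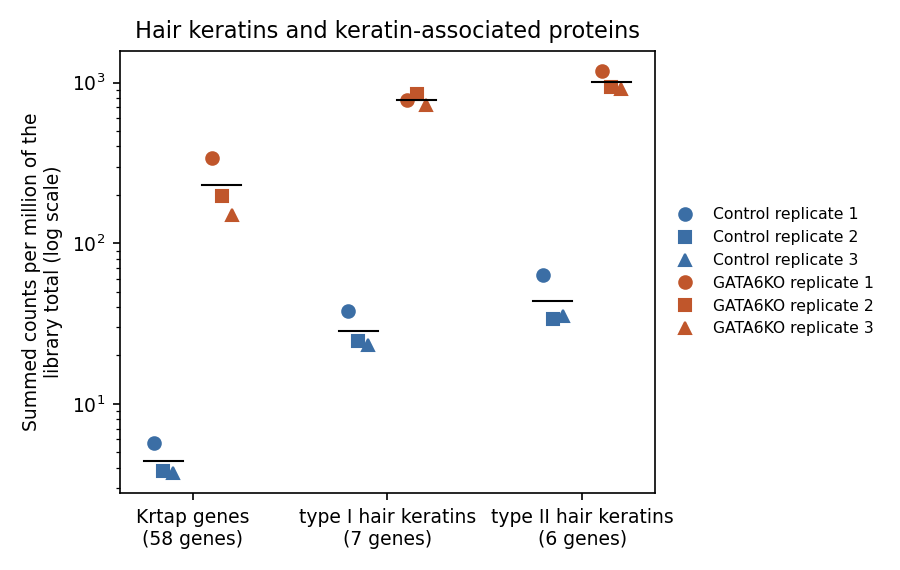
Summed CPM of the plain library total (log axis) for Krtap genes, type I hair keratins and type II hair keratins, with a point per library and a line at the mean of each group. For all 3 sums the 3 GATA6KO libraries lie at least 14.5-fold above the highest Control library.

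Among Wnt targets Nkd1, Notum and Apcdd1 rose, while Lgr5 fell. Of 19 tested Wnt targets, 6 rose and 2 fell (10 and 3 adjusted over the list alone). Nkd1 and Notum, which both restrain Wnt signalling, rose from 82.1 to 603 CPM and from 33.4 to 206 CPM, with log2 fold changes of 2.88 (SE 0.17, adjusted p = 0.000814) and 2.63 (SE 0.10, adjusted p = 0.000214). Apcdd1, another Wnt antagonist, rose by 2.33 (SE 0.40, adjusted p = 0.0158). Axin2, a common readout of the pathway, measured 350 and 422 CPM in Control and GATA6KO (log2 fold change 0.27, adjusted p = 0.125). The list as a set was higher by camera (adjusted p = 0.0189), with adjusted p = 0.809 with an estimated correlation and adjusted p = 0.0707 without GATA6KO replicate 1.

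Of 17 tested intestinal stem cell genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.684). Besides Lgr5, Prom1, a membrane protein of progenitor cells, fell from 296 to 132 CPM (log2 fold change -1.17, SE 0.13, adjusted p = 0.00402). Lrig1, a restraint on growth factor receptors, fell by 0.54 (adjusted p = 0.0475), and Rnf43, a ligase that removes Wnt receptors, rose by 0.54 (adjusted p = 0.0264). Lrig1, Rnf43 and Apcdd1 were not called without Control replicate 1, 2 or 3, at adjusted p of up to 0.184, and Lrig1 also not without GATA6KO replicate 1 or 2 (adjusted p = 0.0594 and 0.0717).

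Genes of the BMP pathway were mostly higher among those that changed. Of 17 tested, 5 rose and 1 fell (6 and 3 adjusted over the list alone). Msx2, a homeobox target of BMP signalling, rose from 1.02 ± 0.05 to 20.3 ± 7.77 CPM (SD, n = 3 each; log2 fold change 4.32, SE 0.32, adjusted p = 0.00153). The ligand Bmp4 rose by 2.89 (SE 0.66, adjusted p = 0.0372), the decoy receptor Bambi rose by 1.56 (SE 0.19, adjusted p = 0.00509), and the ligand Bmp8b fell by 1.91 (SE 0.16, adjusted p = 0.00194). Bmp4 lies on chromosome 14. Of the Id genes, which are BMP targets in this list, Id4 rose by 1.27 (edgeR adjusted p = 0.0441). Id1, Id2 and Id3 were not called, with log2 fold changes of 0.08, 0.31 and 0.14 (adjusted p = 0.73, 0.289 and 0.574). Camera gave adjusted p = 0.0793 for the list, which passed without Control replicates 1, 2 and 3 (adjusted p = 0.05, 0.0367 and 0.0403) and without GATA6KO replicate 2 (adjusted p = 0.00998).

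The receptor Notch1 and the glycosyltransferase Lfng rose by 1.25 and 1.01 (adjusted p = 0.00654 and 0.00617). They were the 2 genes called of 11 tested in the Notch list, with 0 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.455). That list holds receptors and ligands as well as targets. Of 16 genes tested in the TGF-beta list, which also holds ligands and receptors, 1 rose and 2 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.455). Among them were the receptor Tgfbr1, which rose by 0.57 (adjusted p = 0.0431), and the collagen Col4a2, which fell by 0.55 (adjusted p = 0.0453). Bmp4, Tgfbr1 and Col4a2 were not called without Control replicate 1, 2 or 3, at adjusted p of up to 0.199. Tgfbr1 and Col4a2 were also not called without GATA6KO replicate 2 (0.0593 and 0.0539) or 3 (0.0689 and 0.0913).

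Markers of absorptive intestinal cells moved in both directions, 3 higher and 4 lower of 15 tested (4 and 6 adjusted over the list alone; camera adjusted p = 0.510). The sodium-proton exchanger Slc9a3 rose from 8.90 to 96.6 CPM (log2 fold change 3.45, SE 0.31, adjusted p = 0.00225) and the aminopeptidase Anpep from 0.161 to 2.37 CPM (log2 fold change 3.85, adjusted p = 0.0286). The intestinal alkaline phosphatase Alpi fell from 1.41 to 0.0878 CPM (log2 fold change -3.94, adjusted p = 0.0206), and the mucin Muc3 from 8.85 to 1.09 CPM (log2 fold change -3.01, adjusted p = 0.00875). Among 6 Paneth cell and antimicrobial genes, 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.510). The stress protein Nupr1 fell from 413 to 146 CPM (adjusted p = 0.0259), the phospholipase Pla2g2a fell by 2.41 (adjusted p = 0.0102), the nitric oxide synthase Nos2 fell by 3.52 (adjusted p = 0.0277), and the lectin Itln1 rose by 1.62 (adjusted p = 0.0133).

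Other intestinal lineages had few called markers. Of 12 goblet and secretory genes, 1 rose (1 adjusted over the list alone), which was Bcas1, from 11.6 to 74.5 CPM (adjusted p = 0.00795; camera adjusted p = 0.896). Of 3 tuft genes, 1 rose (1 higher and 1 lower adjusted over the list alone), the actin-binding Avil, from 8.03 to 41.8 CPM (adjusted p = 0.00656; camera adjusted p = 0.896). A single enteroendocrine gene was expressed enough to test, Isl1, at 2.12 and 6.77 CPM (edgeR adjusted p = 0.0591). With 1 gene tested, a call over the list alone has no adjustment, and its unadjusted p was 0.00832. Of 19 intestinal lineage transcription factors, 3 rose and 1 fell, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.795). Hnf4g, the paralog of Hnf4a, fell by 3.71 (SE 0.60, adjusted p = 0.0136), while the forkhead factor Foxa2 rose by 1.86 (SE 0.24, adjusted p = 0.00665) and Ehf by 0.70 (adjusted p = 0.00944).

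Of the 13 lineage genes given here as changed, Slc9a3, Muc3 and Avil were called without each library in turn. The other 10 were not called without 1 or more of Control replicates 1, 2 and 3, at adjusted p of up to 0.142 (Anpep). Alpi and Nupr1 were also not called without GATA6KO replicate 3 (adjusted p = 0.0542 and 0.0589).

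Genes of the fetal and regenerative intestine did not move as a set, with 3 higher and 4 lower of 22 tested (5 and 6 adjusted over the list alone; camera adjusted p = 0.407, and adjusted p = 0.00618 without GATA6KO replicate 2). The tetraspanin-like Tm4sf1 fell by 3.81 (adjusted p = 0.00921), the growth factor Areg from 101 to 21.7 CPM (adjusted p = 0.0345) and the interleukin antagonist Il1rn from 231 to 112 CPM (adjusted p = 0.0161), while Ly6d rose by 1.79 (adjusted p = 0.00893). YAP targets were lower by camera (adjusted p = 0.00131, and adjusted p = 0.696 with an estimated correlation), with 1 higher and 7 lower of 19 tested (1 and 7 adjusted over the list alone). The ectonucleotidase Nt5e fell by 4.40 (adjusted p = 0.0267), tissue factor F3 from 97.5 to 26.4 CPM (adjusted p = 0.0413) and the kinase Lats2 by 0.73 (adjusted p = 0.0195), while Nuak2 rose by 0.86 (adjusted p = 0.0156). Lats2 lies on chromosome 14.

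Of 12 squamous and stratified epithelium genes, 2 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.896). Krt15, a keratin of basal cells, rose from 3.89 to 104 CPM (log2 fold change 4.74, SE 0.38, adjusted p = 0.00183) and Krt13 by 0.64 (adjusted p = 0.0468), while Krt4 fell by 0.60 (adjusted p = 0.0127) and Sfn fell by 0.42 (adjusted p = 0.0459). Of 5 gastric and foregut genes, 1 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.896). The stomach secretory gene Gkn1 rose to 2.33 ± 0.877 CPM from 4 counts over the 3 Control libraries (log2 fold change 5.47, adjusted p = 0.00551), and Vsig1 fell by 1.71 (adjusted p = 0.0368).

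Of the 14 fetal, YAP, squamous and gastric genes given here as changed, Krt15 and Gkn1 were called without each library in turn. The other 12 were not called without 1 or more of Control replicates 1, 2 and 3, at adjusted p of up to 0.203 (Krt13). Further losses occurred for F3 without GATA6KO replicate 1 (adjusted p = 0.0609), for Areg and Sfn without replicate 2 (0.0603 and 0.0713), and for Nt5e, Krt13 and Sfn without replicate 3 (0.0515, 0.0692 and 0.0756).

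Cldn2, Cldn15, Cldn4 and Krt18 fell. Of 19 epithelial adhesion and keratin genes tested, 11 fell and 0 rose (15 and 0 adjusted over the list alone), and camera called the list lower (adjusted p = 4.57e-07, and adjusted p = 0.696 with an estimated correlation). Besides Cldn2, the claudin Cldn15 fell from 4.63 to 0.343 CPM (log2 fold change -3.74, SE 0.37, adjusted p = 0.00305) and Cldn4 from 350 to 136 CPM (log2 fold change -1.37, SE 0.17, adjusted p = 0.00559). The keratin Krt18 fell from 1126 to 629 CPM (log2 fold change -0.84, SE 0.12, adjusted p = 0.00971). Over 9 claudin genes tested, 6 fell and 2 rose (Fisher's exact test adjusted p = 0.000216 for those that fell, tested after the values had been seen). Of these 6, only 3 were called without Control replicate 1, and likewise 3 without Control replicate 2 or 3.

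Laminin, integrin and protease genes were lower by camera (adjusted p = 0.00131), with adjusted p = 0.809 with an estimated correlation and adjusted p = 0.0971 without GATA6KO replicate 1. Of 16 tested, 6 fell and 0 rose (6 and 0 adjusted over the list alone). The collagen-binding integrin Itga2 fell from 101 to 11 CPM (log2 fold change -3.20, SE 0.24, adjusted p = 0.00153), the adhesion molecule L1cam from 72.0 to 37.3 CPM (adjusted p = 0.00494), the laminin Lama5 from 462 to 246 CPM (adjusted p = 0.0215) and the collagenase Mmp13 from 1.5 to 0.321 CPM (adjusted p = 0.0385). Of 6 epithelial-mesenchymal transition genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.896). The gene that rose was fibronectin Fn1, from 7.82 ± 1.70 to 106 ± 84.7 CPM (log2 fold change 3.75, adjusted p = 0.0124). Krt18, Fn1, Mmp13 and Lama5 were not called without 1 or more of Control replicates 1, 2 and 3, at adjusted p of up to 0.146.

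Ddit3, Atf3, Dusp1 and Fos fell. Of 19 immediate early and stress genes tested, 6 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 5.74e-07, and adjusted p = 0.696 with an estimated correlation). The stress factors Ddit3 and Atf3 fell from 80.0 to 12.4 CPM and from 67.1 to 15.9 CPM (adjusted p = 0.0370 and 0.0147). The phosphatase Dusp1 and the AP-1 factor Fos fell from 58.7 to 16.8 CPM and from 68.8 to 22.4 CPM (adjusted p = 0.0218 and 0.0183).

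Of 18 MAPK output genes, 1 rose and 4 fell, with 1 and 8 adjusted over the list alone. The list was lower by camera (adjusted p = 0.0242, and adjusted p = 0.809 with an estimated correlation), though not without GATA6KO replicate 3 (adjusted p = 0.166). The receptor Epha2 fell from 372 to 142 CPM (adjusted p = 0.0190), Spry4 by 1.21 (adjusted p = 0.0131), Dusp4 by 1.14 (adjusted p = 0.0436) and Hbegf by 0.92 (adjusted p = 0.0124). Of 14 p53 targets, 2 fell and 0 rose (2 and 0 adjusted over the list alone). This list was lower by camera (adjusted p = 0.0242, and adjusted p = 0.696 with an estimated correlation), though not without GATA6KO replicate 2 or 3 (adjusted p = 0.0585 and 0.0544). The apoptosis gene Pmaip1 fell from 69.4 to 21.6 CPM (log2 fold change -1.69, SE 0.17, adjusted p = 0.00306), and Perp fell by 0.47 (adjusted p = 0.0258).

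None of 18 hypoxia and glycolysis genes passed the test (0 adjusted over the list alone), yet camera called the list lower (adjusted p = 0.000172, and adjusted p = 0.809 with an estimated correlation). The 2 most abundant members, Eno1 and Ldha, measured 3740 and 3070 CPM in Control and 2865 and 2485 CPM in GATA6KO (adjusted p = 0.198 and 0.367), with GATA6KO replicate 1 at 3602 and 3335 CPM. Without GATA6KO replicate 1 the median log2 fold change of the list went from -0.65 to -1.01. Of the 10 stress, MAPK and p53 genes given as changed, Pmaip1 alone was called without each library in turn. The other 9 (Ddit3, Atf3, Dusp1, Fos, Epha2, Spry4, Dusp4, Hbegf and Perp) were not called without Control replicate 1, 2 or 3, at adjusted p of up to 0.154. Dusp4 was also not called without GATA6KO replicate 2 or 3 (adjusted p = 0.0778 and 0.0833), nor Ddit3 without GATA6KO replicate 3 (adjusted p = 0.0862).

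Of 13 transcripts of the mitochondrial genome tested, 4 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00131, and adjusted p = 0.809 with an estimated correlation). The cytochrome gene mt-Cytb rose from 970 to 2141 CPM (log2 fold change 1.14, SE 0.23, adjusted p = 0.0259) and the oxidase subunit mt-Co2 from 2020 to 3140 CPM (adjusted p = 0.0316). The remaining called members were mt-Atp8 and mt-Nd1, with log2 fold changes of 0.78 (adjusted p = 0.0229) and 0.84 (adjusted p = 0.0498). Of 17 fatty acid oxidation and PPAR genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.795). The kinase Pdk4 rose from 0.460 to 3.54 CPM (adjusted p = 0.0200) and the thioesterase Acot1 by 1.58 (adjusted p = 0.0244), while the coactivator Ppargc1a fell by 1.08 (adjusted p = 0.0105).

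Of 18 cholesterol synthesis genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.376, and adjusted p = 0.0165 without GATA6KO replicate 1). Of 20 cell cycle genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.896), the replication licensing gene Mcm2, from 156 to 209 CPM (adjusted p = 0.0270). None of the 8 mitochondrial, metabolic and cell cycle genes given as changed was called without Control replicate 1, 2 or 3, at adjusted p of up to 0.199 (mt-Nd1). The 4 mitochondrial genes were also not called without GATA6KO replicate 3 (adjusted p of 0.0504 to 0.108), nor mt-Nd1 without GATA6KO replicate 2 (adjusted p = 0.0823).

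Antigen presentation and inflammatory genes changed in small numbers. Of 11 MHC and antigen presentation genes, the loading factor Tapbp rose from 15.4 to 38.2 CPM (adjusted p = 0.00878) and the class I gene H2-K1 fell from 342 to 174 CPM (adjusted p = 0.0273), which made 1 and 1 (1 and 1 adjusted over the list alone; camera adjusted p = 0.795). Of 14 inflammatory chemokine and NF-kB genes, 2 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.928). Among them the cytokine Il18 rose by 2.29 (adjusted p = 0.00971), the chemokine Cxcl16 fell by 0.98 (adjusted p = 0.0181), Tnfaip3 fell by 0.75 (adjusted p = 0.0189) and Nfkbia fell by 0.49 (adjusted p = 0.0449). None of 17 interferon response genes passed the edgeR test (0 adjusted over the list alone; camera adjusted p = 0.896). Irf1, an interferon-induced transcription factor, measured 26.5 and 30.2 CPM (adjusted p = 0.495).

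Markers of other cell types mostly had too few counts to test. None of 12 fibroblast markers and 1 of 12 leukocyte markers had enough counts to test. That was Cd68, also expressed outside leukocytes, which fell from 11.9 to 3.43 CPM (adjusted p = 0.0190). With 1 gene tested, a call over the list alone has no adjustment. Of 3 endothelial markers tested, 0 passed the edgeR test (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.896), with Egfl7 at 5.14 and 5.05 CPM and Vwf at 2.31 and 4.28 CPM (adjusted p = 0.946 and 0.0772). Of 4 hepatocyte markers, transferrin Trf fell from 8.21 to 2.15 CPM (adjusted p = 0.0496) and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.795). None of the 8 immune and other-cell genes given as changed was called without each of Control replicates 1, 2 and 3, at adjusted p of up to 0.176 (Nfkbia). H2-K1 was also not called without GATA6KO replicate 3 (adjusted p = 0.0641), Nfkbia without GATA6KO replicate 2 (0.0517) and Trf without GATA6KO replicate 1 (0.0739).

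Over the 30 lists that camera could test, 9 passed, 2 higher and 7 lower. When the libraries were split so that each side held both groups, camera still called 1 to 8 lists. Calls of lists at the preset correlation are thus not by themselves evidence of a group difference. With an estimated correlation 0 passed by camera, with a lowest adjusted p of 0.696 and 1 list at an unadjusted p under 0.05. By fry, which tests whether genes of a list move 1 way on balance, 3 passed. In 5 lists the median, the mean and the test differed in sign: intestinal stem cell, goblet and secretory, gastric and foregut, epithelial-mesenchymal transition, and fatty acid oxidation and PPAR. Camera called none of these 5 lists.

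**Figure D5:**
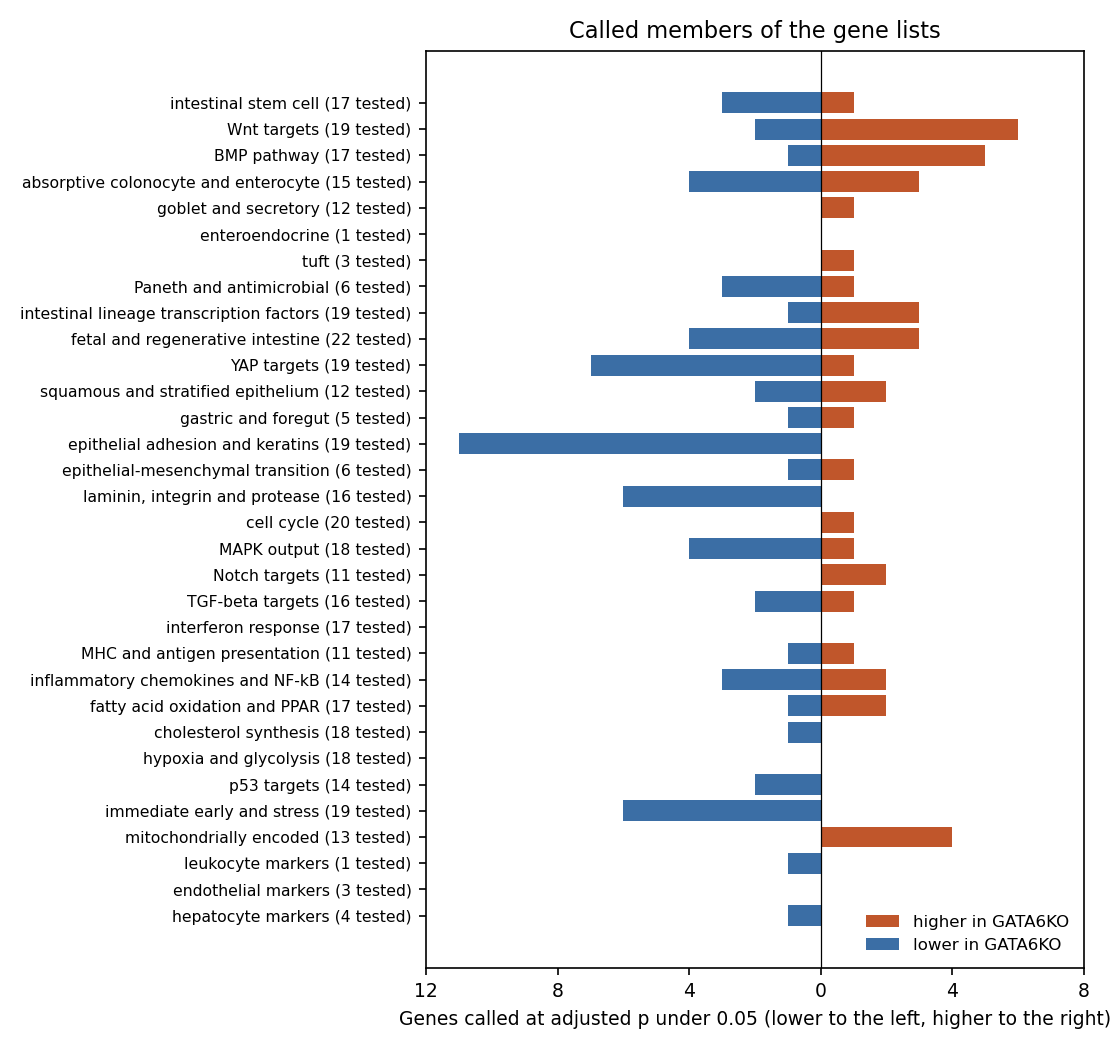
Bars give the number of genes of each list called at an adjusted p under 0.05, with genes lower in GATA6KO to the left of 0 and genes higher to the right, and the number tested in parentheses. Epithelial adhesion and keratins had the most genes lower, 11 of 19, and Wnt targets the most genes higher, 6 of 19.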

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

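The counts of symbol families, the fit with a spread per group and the fit without chromosome 14 were chosen after the data were seen. Among the 97 named genes called and the gene lists, no called result turned its direction under any alternative run. Not all of the 1823 called genes were checked for this. Called genes had groups that did not overlap, so leaving out a library could hardly turn their direction. DESeq2 called 3155 genes (1708 higher, 1447 lower), the test against a fold of 1.5 called 525 (340 and 185), and the cause was not tested for DESeq2, while the fold test asks for a larger change by construction. Of the 1823 genes, 1795 were among the DESeq2 calls. Leaving out a library gave 332 to 4360 genes (202 to 2235 higher, 130 to 2125 lower), with fewer samples by construction. The lowest count came without Control replicate 3 and the highest without GATA6KO replicate 1. Fewer samples do not explain a count above 1823, and the cause of that rise was not tested. The other fits, apart from the replicate block given below, gave 1706 to 1986 genes.

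With the replicate block 827 genes were called (480 and 347) and Gata6 had a log2 fold change of -1.03 (adjusted p = 0.0915). Libraries with the same number did not deviate together (correlations of deviations across genes -0.01, 0.07 and -0.09), and only the libraries with number 2 correlated best with their own number, so the number is not taken to pair samples. Gata6 was not called with the library total alone (log2 fold change -0.91, adjusted p = 0.0573) or against a fold of 1.5 (-0.99, adjusted p = 0.299). Leaving out a library gave -1.18 to -0.75, and the cause was not tested.

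The Pcdhb genes that rose numbered 5 with the stricter filter, 5 with the replicate block and 1 to 12 with a library left out. The claudins that fell numbered 3 against a fold of 1.5 and 3 to 6 with a library left out. With an estimated correlation 0 lists passed, and by fry 3. Of 97 named genes called, 30 were called in every fit and 41 in every fit of all 6 libraries. The loss was largest without Control replicates 1, 2 and 3, where 58, 59 and 63 named genes other than Gata6 lost the call. The edgeR test fits the same spread to both groups, and Control spread less (median SD 0.0950 against 0.279 on the log2 scale). Without any Control library that spread rests more on GATA6KO, so such a loss need not mean that an effect depends on that library. How much of the loss this accounts for was not tested. Depth was within 1.5-fold between libraries. Single genes with under 10 counts in a library, such as most Krtap genes in Control, have fold changes set partly by counting error.

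For gene lists the value is the median log2 fold change of the list. With an estimated correlation and with fry the medians stay as they are and only the test changes. The estimated correlation left these lists below the call: Wnt targets (0.54), YAP targets (-0.52), epithelial adhesion and keratins (-0.47), laminin, integrin and protease (-0.43), MAPK output (-0.15), hypoxia and glycolysis (-0.65), p53 targets (-0.37), immediate early and stress (-0.82) and mitochondrially encoded (0.74). Fry kept Wnt targets and epithelial adhesion and keratins and added the BMP pathway (0.36). The BMP pathway was also called with no filter (0.62) and with the replicate block (0.32). With no filter, absorptive (-0.98) and Paneth and antimicrobial genes (-1.28) were called too, and the cause was not tested.

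With a library left out, medians lay between 0.45 and 0.73 for Wnt targets, 0.41 and 0.72 for the BMP pathway, -0.64 and 0.0541 for fetal and regenerative intestine, -0.71 and -0.26 for laminin, integrin and protease, -0.38 and -0.10 for MAPK output, -0.27 and 0.0163 for cholesterol synthesis, -1.01 and -0.47 for hypoxia and glycolysis, -1.27 and -0.81 for immediate early and stress, and -0.43 and -0.27 for p53 targets.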

Other observations

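The genes singled out in this part were chosen after their values were seen, and of the tests given here only that of genes next to the keratin clusters was set before its result was seen. Foxn1 and Dlx3, transcription factors of hair shaft differentiation, rose from 20.7 to 69.5 CPM (log2 fold change 1.75, SE 0.23, edgeR adjusted p = 0.00679) and from 18.2 to 78.5 CPM (log2 fold change 2.11, SE 0.32, adjusted p = 0.0113). Hoxc13, one of the skin and hair follicle markers used below, had 0 counts in every library. Lef1, a Wnt-dependent factor of the hair matrix, rose by 1.91 (adjusted p = 0.00654), and Dsg4, the desmoglein of the hair shaft, from 2.89 to 42.6 CPM (adjusted p = 0.00305). The cornified envelope gene Lor rose by 2.10 (adjusted p = 0.00194). Gata3, a GATA factor of the skin and hair follicle, fell from 10.9 to 2.06 CPM (adjusted p = 0.0365). Dlx3 and Gata3 were not called without Control replicate 1, 2 or 3 (adjusted p of up to 0.143), nor Gata3 without GATA6KO replicate 2 (adjusted p = 0.0646).

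All 9 tested genes of the clustered protocadherin group Pcdhb, cell surface adhesion proteins encoded side by side on chromosome 18, rose from low levels, with Pcdhb17 going from 0.548 to 4.19 CPM (log2 fold change 2.93, SE 0.30, adjusted p = 0.00327). Fisher's exact test of the family gave adjusted p = 7.91e-09, and these genes are similar in sequence. A gene of low level in Control passes the filter mainly when it is higher in GATA6KO, so this p depends partly on the filter. Only 4, 4 and 1 of them were called without Control replicates 1, 2 and 3. Wnt ligands and receptors also included genes that rose: Wnt5b from 1.91 to 13.8 CPM (adjusted p = 0.00145), Wnt3 from 0.149 to 1.44 CPM (adjusted p = 0.00490) and the receptor Fzd10 from 8.97 to 68.8 CPM (adjusted p = 0.00478). The Wnt and Fzd families did not pass the family test (adjusted p = 0.330 and 0.414). The genes with the smallest p-values were Dapl1, from 5.94 ± 0.387 to 208 ± 28.9 CPM (log2 fold change 5.13, SE 0.14, adjusted p = 8.04e-05), and Hpgd, which degrades prostaglandins, from 42.3 ± 2.64 to 286 ± 11.1 CPM (log2 fold change 2.76, SE 0.09, adjusted p = 0.000127).

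The increase of hair keratin and Krtap genes was set against 3 technical explanations. If reads had only been divided otherwise among near-identical copies, family sums would not have moved, yet in the sum that moved least the lowest GATA6KO library lay 14.5-fold above the highest Control library. Pieces of skin or hair follicle would bring all their abundant transcripts, yet the median of 14 markers was at most 0.0019% of the hair keratin and Krtap counts in a GATA6KO library, with Krt5, Krt1, Krt17, Krt71, Krt25, Krt28, Trp63, Dsc3 and Hoxc13 at 7 counts or fewer together and Krt14, Krt15, Krt6a, Lor and Dsg4 giving nearly all of the sum (7.48%, 13.96% and 8.23% in GATA6KO replicates 1 to 3). Extra copies of the clusters would raise neighbours too, and 106 other tested genes within 1 Mb had a median log2 fold change of 0.10 (bootstrap SE 0.06), with 23 higher (21.7%, against 6.92% of all genes tested) and 6 lower. These values argue against a changed division of reads and against extra cluster copies as the whole cause. For skin pieces the median and its bounds replaced a sum of the same 14 markers that decided nothing and a sum of the 9 scarce ones. With 9 of 14 markers near 0 the median had to lie near 0, so no conclusion is drawn from it. The scarce counts go only against pieces that carry those 9 transcripts in quantity. Cells of the hair shaft alone and a difference between cultures, by the edit or otherwise, stay open, untested.

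The low level of chromosome 14 in GATA6KO replicate 2 could come from loss of a copy of that chromosome. Copy number, and the share of cells with such a loss, were not measured. Of 12 windows of 10 Mb with at least 5 expressed genes, 11 (91.7%) lay at a median log2 ratio under -0.5. Of 355 expressed genes, 339 lay below the Control mean. The medians of GATA6KO replicates 1 and 3 were -0.09 and 0.04, and no biological explanation was tested. On this chromosome 35 genes were called lower and 9 higher, and without it 1880 genes were called.

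Unedited cells in the GATA6KO cultures could account for the Gata6 transcript that remained. Such cells, if they kept Control levels, would hold every gene at no less than the share that Gata6 kept. Of 9335 other genes with at least 10 CPM in Control, 78 lay under that share in all 3 GATA6KO libraries, by 95% Poisson bounds. These bounds cover counting error only. Cldn2 stayed at no more than 1.73% of the lowest Control library. These values argue against unedited cells as the whole source. A transcript that still forms from an edited gene stays open and was not tested.

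The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 1823 genes and the highest of the other 9 called 0, so 1 of 10 splits reached the real count. For Krtap genes the real split called 20 and the highest other 0 (1 of 10 splits). Each other split holds Control and GATA6KO libraries on both sides. The group difference then enters the spread and lowers the calls of genes by construction, so no conclusion is drawn from the 0 calls. For gene lists by camera the real split called 9 and the highest other 8 (1 of 10 splits). The other 9 splits called 8, 8, 4, 8, 5, 1, 1, 6 and 7 lists, though they called 0 genes. Camera at the preset correlation thus called lists readily in mixed groups, and the count of 9 does not by itself show a group difference.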
